A study of Mus musculus with 9 samples.

How the data were processed

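Messenger RNA was sequenced from 9 sorted samples of mouse bone marrow. Per the labels' protocols, lineage-negative cells were stained and sorted as megakaryocyte progenitors (cKit+, Sca1-, CD150+, CD41+), split by reporter colour, or as Tom+ stem cells (cKit+, Sca1+, CD150+, Flk2-). RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit, which the same protocol describes as using Tn5. The submitters' processing notes name the mm10 build and the tools Bowtie2, STAR and DESeq, without their roles or versions. The counting tool, gene annotation, scaling method and choice of genes are not given in the sources used here. The labels give the age of the old mice as 18 to 20 months in one field and as the upper of these ages in another.

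The authors deposited 1 table of normalized counts, a signal scaled per library, with 2402 genes as columns and 9 rows without names. No column or label ties a row to a sample. Rows were not assigned by their order or their values, so no row has a group, n per group, mean or SD, and no test between groups was run. The main comparisons planned before the data were examined (old Tom+ against old GFP+ MkP, old against young GFP+ MkP, and old Tom+ MkP against old Tom+ HSC) and 2 secondary ones, all with limma on log2 values, were therefore not run. The same holds for their set tests and alternatives. Whether the samples came from separate animals is not stated.

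Within each row the low values were whole multiples of 1 step, between 0.724 and 1.96 normalized counts per read. Dividing by the step gave whole reads within a tolerance of 0.1 for 100% of values in each library. The 9 libraries had 2017666, 1868577, 1790670, 2050047, 3854998, 2931805, 3164734, 2749320 and 4373460 reads in the table, in row order. These are totals over the genes of the table, not library depths. A count of 0 allows up to 3 reads, or 2.17 to 5.89 normalized counts depending on the library. Intervals of a ratio between 2 libraries are exact conditional binomial intervals at 95%. They cover counting error only, not biological or PCR variation, and not the choice of the highest and lowest of 9 libraries.

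The statistics that follow, unlike the gene lists, were chosen after the table had been seen. For each gene the median, the lowest and the highest library were taken. Genes with at least 10 normalized counts in at least 2 libraries (2341) entered the range statistics. The range was the difference of the highest and the lowest log2 value with a pseudocount of 1. The pseudocount understates the range of low genes that are above 0 in every library. For a gene at 0 in a library it sets the size of the range and can widen it. Ranges of single genes are ratios of deposited values. Differences beyond counting error were tested per gene with a chi-square test of recovered reads against 1 rate per read, adjusted over 2341 genes at 0.05. Each fixed list with at least 5 genes that passed the filter (13 lists) was placed among 10000 random lists of the same size drawn from the table within 20 bins of mean expression, as a description of these libraries. Since the choice of the 2402 genes is unknown, the table is not a genome-wide background. The 26 gene lists were fixed before the data were examined; they include markers of other lineages, and several share members. Members were matched by symbol, and 0 more were found by a synonym. No mitochondrially encoded gene and no gene of the sex check list (Xist and Y-linked genes) was matched, and 11 other lists had fewer than 5 members. Antigen presentation, B lineage, mast cell, macrophage, stromal and ribosomal protein lists had 1 measured gene each.

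The planned rule for naming genes needed p-values between groups and could not be applied. The genes named were chosen by a rule set after the table had been seen. It takes the sort markers, the 3 members of each list with the highest median and the 3 with the widest range (all members of lists under 5), the 10 genes with the highest median, the 10 with the widest range and a highest value of at least 50, and the 10 with the narrowest range and a median of at least 1000, leaving out unnamed or predicted genes. Some genes that this rule takes are not reported here. Symbols of 2259 genes matched GENCODE M21, which annotates mm10, and coordinates are from there. Reads shared with overlapping genes or paralogs cannot be separated in this table.

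The steps were tested on simulated data drawn for 2341 genes from the mean rates of the real libraries with 200 changed genes. A first version of the search for the step failed this test, where the smallest value of a library was more than 1 read, and was corrected. With the corrected version all simulated reads (100%) were recovered, the chi-square test found 70%, 92%, 98% and 100% of genes changed 1.5-, 2-, 4- and 8-fold in 1 library, and it called 0.747% of unchanged genes. Of 40 unchanged lists, 0 fell outside the central 95%. Apart from the changed genes, the simulated genes were independent and varied by counting error alone. In the real libraries most genes varied by more, so this does not check the percentiles of real lists. Alternatives were another pseudocount (0.5 or 5), no filter or a minimum of 50, values under 3 reads raised to 3 reads in place of a pseudocount, median-of-ratios scaling of recovered reads, scaling to the table total, quantile normalization, each library left out, and libraries 3 and 4 left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.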

Results

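The study asked how megakaryocyte progenitors that arise along different routes in old age compare in their messenger RNA. Megakaryocyte progenitors (MkP) are the bone marrow cells that give rise to megakaryocytes, which release platelets. They were sorted from male mice carrying a Flt3-driven Cre recombinase and a dual-colour reporter, called FlkSwitch mice. In this reporter a cell shows the red protein Tomato (Tom) until it or an ancestor has made Cre, and the green protein GFP afterwards. The labels describe 9 samples in 4 groups, with 3 samples of GFP+ MkP from young mice of 3 months, and 2 samples each of GFP+ MkP, Tom+ MkP and Tom+ haematopoietic stem cells (HSC) from old mice of 18 to 20 months. The deposited table holds normalized counts of 2402 genes in 9 rows, and the rows carry no sample names. No row could therefore be matched to a sample or a group, and the 5 comparisons between groups that the design implies were not made. What follows gives the spread of each gene over the 9 unnamed libraries, which mix cell types, ages and reporter states. Libraries are numbered 1 to 9 by their row, as a name only.

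The 9 libraries had 1790670 to 4373460 reads on the genes of the table, recovered from the step between neighbouring low values. Of the 2402 genes, 2341 had a normalized count of at least 10 in at least 2 libraries and 1688 reached 10 in all 9. Over these 2341 genes the median ratio of the highest to the lowest library was 6.16-fold, on normalized counts with 1 added, and 1555 genes (66.4%) had a range of at least 4-fold. The count of such genes was 443 of 2133 without libraries 3 and 4, a setting chosen after seeing the data. Reads differed between libraries beyond counting error for 2311 genes (chi-square test with Benjamini-Hochberg adjustment), and 30 genes did not pass it. This test compares libraries, not conditions, and takes the deposited scaling as given. An offset in the scaling of a library would also count as a difference, and the test was not repeated under other scalings. None of the 36 pairs of libraries agreed within sampling noise, with reads of each pair scaled by their table totals. The closest pair had on average 13.4 times the chi-square per gene that counting alone gives. No library was therefore treated as a copy of another and all 9 were kept, which does not show that they are independent samples.

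Genes of megakaryocytes and platelets included the most abundant transcripts of the table, and their levels were far apart between libraries. Itga2b, which encodes the integrin CD41 used in the sort, had the highest median of all genes, 68308 normalized counts, and ranged from 1616 to 77883, a 48.2-fold range (95% exact counting interval 45.7 to 50.9). Pf4, the chemokine platelet factor 4, had a median of 26211 and ranged 44.2-fold, from 899 to 39766. Gp1bb, a subunit of the von Willebrand factor receptor, ranged from 133 to 12267 with a median of 5662. Treml1, a receptor of platelet granules, ranged from 21.7 to 2848, and F2rl2, a thrombin receptor, from 14.2 to 6746, a 477-fold range (interval 273 to 923). Fermt3, which activates platelet integrins, had a narrower range of 3.68-fold around a median of 27308. Of the 15 measured list members, 13 had a range of at least 4-fold, and their median range of 33.9-fold lay at the 99.99th percentile of 10000 random lists matched on expression level, whose median was 4.27-fold. Without library 3 the ranges were 11.9-fold for Itga2b, 28.2-fold for Pf4, 137-fold for F2rl2 and 48.7-fold for Gp1bb (55.6-fold without library 7). Library 4 was also low in these genes. Without libraries 3 and 4 Itga2b lay between 45798 and 77883, Pf4 between 17894 and 39766, F2rl2 between 1985 and 6746 and Gp1bb between 1708 and 12267. The list then lay at the 83.68th percentile. In the mm10 assembly with GENCODE M21, the protein-coding gene Itga2b lies on chromosome 11 from 102453297 to 102470122, and Pf4 on chromosome 5 from 90772435 to 90773383.

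**Figure D1:**
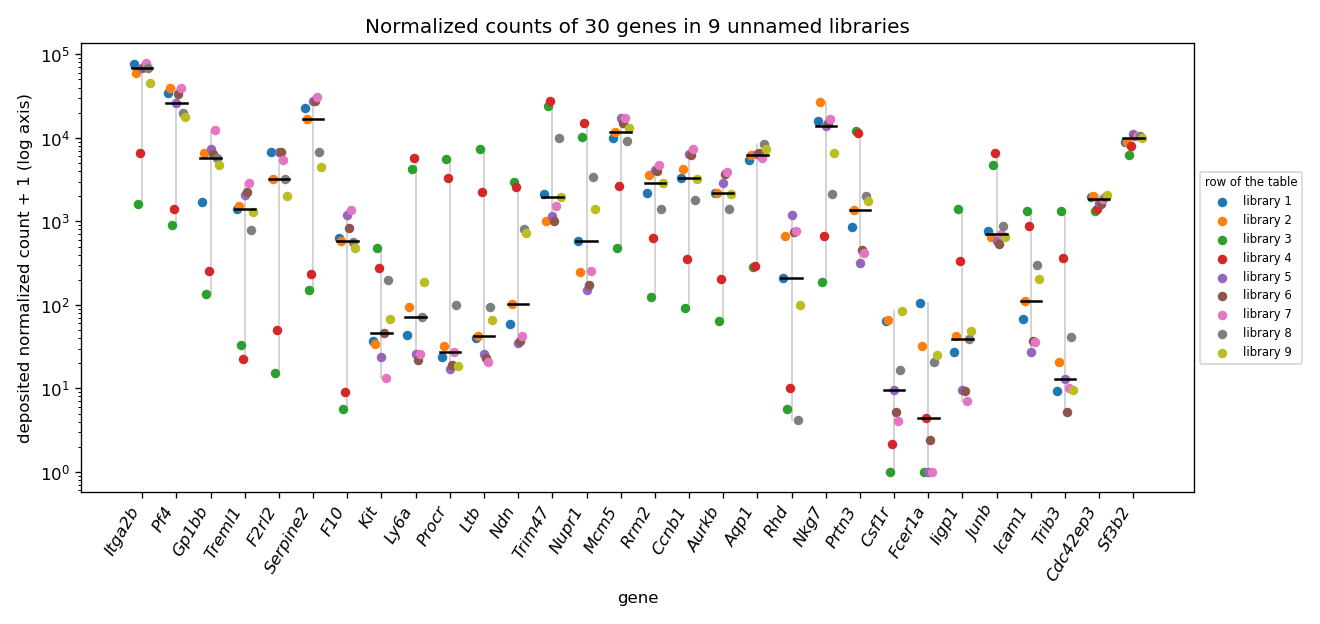
Deposited normalized count plus 1 (vertical log axis) of 30 genes (horizontal axis) in the 9 unnamed libraries; each point is 1 library, coloured by its row in the table, the black bar is the median and the grey line spans the range. Itga2b runs from 1616 to 77883 normalized counts, whereas Sf3b2 stays between 6256 and 11016.

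The list of platelet activation and coagulation genes shares members with the previous list. Serpine2, an inhibitor of thrombin and other serine proteases, had a median of 16934 and ranged 207-fold, from 150 to 31054 (interval 174 to 249). F10, which encodes coagulation factor X, ranged from 4.72 to 1369 around a median of 575. Lat, a signalling adaptor, had a median of 6816 and an 8.27-fold range. Of the 12 members that passed the expression filter, 11 had a range of at least 4-fold, and the median range of 15.2-fold lay at the 99.58th percentile of matched random lists. Without library 3 the ranges were 133-fold for Serpine2 and 171-fold for F10. Without libraries 3 and 4 Serpine2 lay between 4493 and 31054 and F10 between 483 and 1369. The list lay at the 83.25th percentile without libraries 3 and 4, and at the 96.37th under median-of-ratios scaling.

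Several genes of haematopoietic stem cells had a highest value far above their median over the libraries. Of the 14 measured members, 10 had at least 10 normalized counts in all 9 libraries. Procr, the endothelial protein C receptor and a stem cell surface marker, had a median of 26.1 normalized counts and ranged from 16.3 to 5639, a 346-fold range (interval 210 to 619). Ltb, which encodes lymphotoxin beta, had a median of 41.2 and ranged 367-fold up to 7334. Ly6a, the Sca1 antigen that the sort selected against in progenitors and for in stem cells, reached 5772 from a median of 71.3, a 275-fold range (interval 167 to 492). Ndn, an imprinted growth suppressor, ranged from 33.7 to 2994. Trim47 had the highest median of the list, 1969, and ranged 27.1-fold, and Tie1, a receptor tyrosine kinase, ranged 6.08-fold. All 14 measured members had a range of at least 4-fold, and the median range of 79.8-fold lay above all 10000 matched random lists. Without library 3 the median range was 31.1-fold, with 204-fold for Procr and 114-fold for Ltb, and the list lay at the 99.74th percentile without libraries 3 and 4. Procr lies on chromosome 2 from 155751117 to 155755471, and Ly6a on chromosome 15 from 74994877 to 74998031, both protein-coding. Kit, the stem cell factor receptor used in both sorts, ranged 39.2-fold, from 12.3 to 481, around a median of 44.8 (21.1-fold without library 7 and 22.7-fold without library 3), and lies on chromosome 5 from 75574916 to 75656722.

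A list of genes known to be higher in aged stem cells had the widest median range over the 9 libraries, 112-fold over 6 measured members, again above all 10000 random lists. That rank turned on single libraries. Without library 2 the range was 96.8-fold, below the 105-fold of the erythroid list. Without library 4 it was 76.3-fold, below the 79.8-fold of the HSC list. Over all 9 libraries the aged HSC list had 105-fold with values under 3 reads raised to 3 reads. Nupr1, a stress-response transcriptional regulator, ranged from 150 to 15198 with a median of 581. Alcam, an adhesion molecule, was at 0 in 1 library and reached 424, which is 86.2 times the value that 3 reads would give there. Cpne8 had 1 read in its lowest library and reached 623, a ratio of 445 with an interval from 79.6 to 17621 (287 without library 6), and Jam2, a junction protein, reached 612 with 2 reads in its lowest library. Dhrs3, a retinal reductase of the same list, had its spread at a high level, with a median of 8210 and a 9.60-fold range. The members did not vary in 1 direction, which a range does not show. Nupr1, Alcam, Cpne8 and Jam2 were highest in libraries 3 and 4. Dhrs3 (1267 and 1685) and Sdpr (2693 and 910) were lowest there.

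Cell division genes of both lists differed widely between libraries, and the lists were not tested against each other. Mcm5, a subunit of the replicative helicase, ranged 35.9-fold, from 485 to 17384, and Mcm6 had the highest median of the S phase list, 24499, with a 9.57-fold range. Rrm2, a subunit of ribonucleotide reductase, ranged 39.0-fold and Cdc6, which licenses replication origins, 37.5-fold. Ccnb1, which encodes cyclin B1, ranged from 90.8 to 7392, an 81.4-fold range (interval 65.0 to 103), and Aurkb, the kinase aurora B, ranged 63.1-fold, whereas the mitotic kinase gene Plk1 ranged 6.57-fold. The 16 S phase genes had a median range of 11.6-fold at the 99.95th percentile, and the 13 G2/M genes one of 38.7-fold at the 99.98th percentile. Much of this spread rests on library 3. Without it the median ranges were 4.21-fold for S phase and 13.3-fold for G2/M genes, with 3.22-fold for Mcm6, 6.64-fold for Mcm5, 7.52-fold for Rrm2, 13.3-fold for Cdc6, 20.9-fold for Ccnb1 and 19.4-fold for Aurkb. Without libraries 3 and 4 the S phase list lay at the 26.42nd percentile and the G2/M list at the 99.42nd. Mcm5 then lay between 9193 and 17384 and Ccnb1 between 1777 and 7392.

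Genes of other blood lineages were also present. Among 5 measured erythroid genes, Aqp1, a water channel, had a median of 6161 and Rhd, a blood group protein, ranged from 3 reads (3.15) in the lowest library to 1187, a ratio of 377 with an interval from 129 to 1832 (244 without library 5). Ermap ranged from 2.36 to 352, with 5.72 as the lowest value without library 3, and Add2 from 0 to 113. The erythroid list had a median range of 105-fold at the 99.89th percentile. This median is the value of Ermap, which had 2 reads in its lowest library (149-fold without the pseudocount, interval 41.0 to 1237). Since 2 other genes of the list were at 0 in a library, the size of the median range rests on few reads and on the pseudocount. With values under 3 reads raised to 3 reads it was 35.9-fold at the 99.02nd percentile, and the median range was 52.5-fold without library 3 and 36.8-fold without library 4. Without library 4 the list lay at the 97.36th percentile, inside the central 95%. Prtn3, the granule protease proteinase 3, had a median of 1356 and reached 12248, while Csf3r, the granulocyte colony-stimulating factor receptor, ranged from 6.14 to 862. Csf1r, the macrophage colony-stimulating factor receptor, was at 0 in 1 library and reached 82.6, and Cebpa reached 41.2. The 5 granulocyte and monocyte genes had a median range of 42.2-fold at the 95.29th percentile, or 24.1-fold at the 96.86th with values under 3 reads raised to 3 reads, 3 of the genes being at 0 in a library. Whether the list lay inside the central 95% of random lists turned on the setting. It lay above under pseudocounts of 0.5 and 5 (98.14 and 98.45), scaling to the table total (98.48), quantile normalization (99.94), without library 3 (98.10) and without libraries 3 and 4 (99.64). Of the T and NK cell list, Nkg7, a cytotoxic granule protein, had a median of 13914 and a 147-fold range (40.7-fold without library 3 and 91.4-fold without library 2), whereas Lck did not exceed 44.8 and Klrb1c reached 493 from a median of 4.92. Single measured genes of other types stayed low, with Vpreb1 of the B lineage at no more than 12.3, Cd5l of macrophages at 39.8 and Fcer1a of mast cells and basophils at 103, the last with 0 reads in 3 libraries and at most 31.4 without library 1. Without library 9 Cd5l was at most 24.6. Emcn, an endothelial and stem cell sialomucin, reached 322 (213 without library 3).

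**Figure D2:**
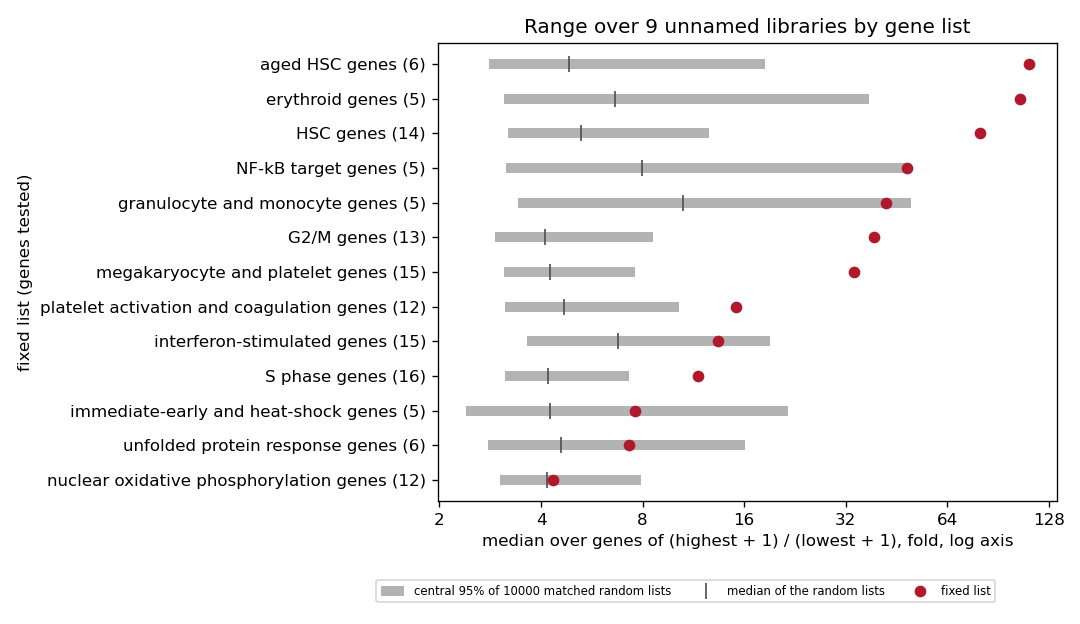
Median over the genes of each fixed list (vertical axis, number of genes tested in parentheses) of the ratio of the highest to the lowest library, as a fold on normalized count plus 1 (horizontal log axis); the grey bar spans the central 95% of 10000 random lists matched on expression level and the tick is their median. Of the 13 lists, 7 lie above the bar, from S phase genes at 11.6-fold to aged HSC genes at 112-fold.

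Stress, inflammatory and metabolic lists lay within the central 95% of random lists over the 9 libraries, some of them only under part of the settings. Interferon-stimulated genes had a median range of 13.4-fold over 15 members (91.41st percentile), with Iigp1, an interferon-inducible GTPase, between 6.14 and 1414 (at most 339 without library 3), Irf7 between 103 and 740 and Bst2 between 113 and 505. Under scaling to the table total this list lay at the 98.70th percentile. Among immediate-early genes, Junb ranged 12.3-fold up to 6617, Zfp36 11.3-fold up to 4468 (6.87-fold without library 3) and Ier2 7.60-fold up to 9471, and the 5 members lay at the 81.46th percentile. Of the NF-kB targets, Icam1 ranged from 26.1 to 1318, Bcl3 from 11.2 to 1277 (at most 682 without library 4) and Birc3 from 27.2 to 143 (at most 75.5 without library 3). The list had a median range of 48.7-fold at the 97.44th percentile, at the edge of the central 95% of random lists. It lay above under scaling to the table total (98.53), quantile normalization (98.92), no filter (98.61) and without library 6, 7, 8 or 9 (97.86, 97.54, 98.01 and 97.90), so no call is made for it. With values under 3 reads raised to 3 reads the median range was 29.6-fold, and without library 3 it was 31.2-fold. Il1b was at 0 in 1 library and at most 102. Among unfolded protein response genes (83.32nd percentile), the chaperones Hspa5 and Hsp90b1 ranged 5.61-fold and 5.89-fold, Sdf2l1 58.9-fold, Asns 9.10-fold, and Trib3 from 4.20 to 1316. Without library 3 these were 3.16-fold for Hspa5, 13.6-fold for Sdf2l1, 4.05-fold for Asns and 87.2-fold for Trib3 (161-fold without library 6), and the median range of the list went from 7.31-fold to 4.22-fold. Nuclear genes of oxidative phosphorylation had a median range of 4.36-fold (57.64th percentile), with Cox5a between 2221 and 14194, Cox5b between 1765 and 9481, and Atp5o and Atp5g1 ranging 5.22-fold and 5.81-fold. Without library 3 Cox5a ranged 3.62-fold and Cox5b 3.48-fold. Without libraries 3 and 4 this list lay above the central 95% (98.57th percentile). Lists with fewer than 5 measured genes were not tested. Of these, Sqle and Insig1 of cholesterol synthesis ranged 5.18-fold and 4.90-fold and Hmgcs1 2.40-fold, Pgk1 and Slc2a1 of glycolysis 3.74-fold and 3.66-fold, the p53 targets Plk2 from 3.93 to 1327 and Aen 4.06-fold, the ribosomal protein relative Rps27l 5.85-fold, and Tap1, a peptide transporter of antigen presentation, 2.08-fold. Without library 3 Sqle ranged 3.00-fold, Aen 2.50-fold and Plk2 reached 141 (and its lowest value was 6.14 without library 2), and Slc2a1 ranged 2.40-fold without library 9 and 2.43-fold without library 4.

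The genes with the highest medians included several outside the fixed lists. Rap1b, a small GTPase of integrin activation, had a median of 47372 and a 12.2-fold range, and Ppp1ca, a phosphatase subunit, had 41433 and 3.86-fold. Hnrnpf, Zyx, Tuba4a and Ewsr1 had medians of 28794, 28508, 27313 and 25577 and ranges of 2.51-fold to 3.72-fold, with 2.42-fold for Tuba4a without library 3. The widest ranges were in genes with almost no reads in some libraries. Cldn5, a tight junction protein, had 1 read in its lowest library and reached 1897. Efna1 reached 1101, Gem 1050 and Meg3, an imprinted long noncoding RNA, 4332. The size of the highest value turned on 1 library, since Cldn5 reached 891 and Meg3 900 without library 4, and Efna1 672 and Gem 351 without library 3. The wide ranges did not, since libraries 3 and 4 were both high for each of these genes. In any other library Cldn5 was at most 34.6, Meg3 40.9, Efna1 24.1 and Gem 25.35. Unc45b and Kcnj5 were at 0 in 1 library each and reached 810 and 408, which are 193 and 115 times the value of 3 reads there. Without library 3 Unc45b reached 382, and without library 6 Kcnj5 reached 249. The narrowest ranges among genes with a median of at least 1000 were 1.56-fold for Cdc42ep3, 1.57-fold for Nrbp1 and 1.62-fold for Ptpn1. Ccar1, Casp8, Chaf1a, Tcea1, Hnrnpr, Sf3b2 and Ankrd10 followed with 1.65-fold to 1.84-fold.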

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

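All alternatives here were chosen after seeing the data, since those planned beforehand need groups and were not run. No paired analysis was possible because the rows of the table carry no sample names or replicate numbers. The count of 1555 genes with a range of at least 4-fold lay between 1108 (library 3 left out) and 1546 when single libraries were left out, and between 1209 and 1649 under the other pseudocounts, filters and scalings. It was 443 of 2133 genes without libraries 3 and 4. The number of lists above the central 95% of random lists was 7, and 6 to 10 under the alternatives, with 0 below it. Granulocyte genes came above it under both other pseudocounts, scaling to the table total, quantile normalization, without library 3 and without libraries 3 and 4. NF-kB targets did so with no filter, under these 2 scalings and without library 6, 7, 8 or 9, interferon genes under scaling to the table total, and oxidative phosphorylation genes without libraries 3 and 4. Platelet activation genes fell inside the random lists under median-of-ratios scaling (96.37th percentile), and erythroid genes did so without library 4 (97.36). Without libraries 3 and 4, megakaryocyte, platelet activation and S phase genes did so as well (83.68, 83.25 and 26.42), and the cause was not tested. HSC genes, aged HSC genes and G2/M genes stayed at or above the 99.42nd percentile under every alternative run. The NF-kB, granulocyte and erythroid lists had fewer than 5 members at a minimum of 50. So had NF-kB without library 3 or 4 or both, and granulocyte genes without library 2 or 9. These gave no percentile. Counting error limits genes with few reads, such as Cpne8 or Cldn5, whose lowest library had 1 read.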

Other observations

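The tests of read totals and of scaling, and the test of imprinted genes with the noticed genes included, were chosen after the results were seen. The test of imprinted genes without them was set before.

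The values of several genes fell into separate clusters of libraries. Each library is given by its row, and no row is assigned to a group of the study. In row order, Itga2b had 76148, 60607, 1616, 6543, 68842, 69704, 77883, 68308 and 45798 normalized counts, and Ltb had 39.4, 41.2, 7334, 2266, 25.0, 22.4, 20.0, 93.3 and 64.5. Ccnb1 had 3291, 4267, 90.8, 354, 6441, 6224, 7392, 1777 and 3176. For 12 of 14 HSC genes the highest value was in library 3 and for the other 2 in library 4. All 16 S phase and all 13 G2/M genes were lowest in library 3. Of the 15 interferon-stimulated genes, 12 were highest in library 3 and 3 in library 4. Over all 2341 genes, 1030 were highest in library 3, 286 in library 4, and 856 were lowest in library 3, so many genes of any list have their extremes there.

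Other genes divided the remaining libraries differently; they were picked after their values were seen. Rhd had 212, 665, 4.72, 9.15, 1187, 744, 768, 3.15 and 98.5 in row order, and Ermap, another erythroid gene, had 118, 234, 2.36, 5.72, 352, 316, 167, 10.5 and 50.7. Csf1r had 64.0, 64.8, 0, 1.14, 8.69, 4.20, 3.07, 15.7 and 82.6, and Fcer1a, a subunit of the IgE receptor, had 103, 31.4, 0, 3.43, 0, 1.40, 0, 19.9 and 23.9. Hoxb5, a stem cell homeobox gene, had 9.84, 11.8, 400, 223, 3.26, 5.59, 3.07, 195 and 112. Trim47 had 9887 in library 8 and 1969 in library 9, and Gp1bb had 1708 in library 1 against 6673 in library 2, while Gp5, of the same receptor complex, had 8982 and 9211.

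Libraries 3 and 4 lay apart from the other 7. Rank correlations were taken across 2341 genes, which are not independent replicates. Libraries 3 and 4 had 0.962 with each other and 0.642 to 0.875 with the others, which reached 0.941 to 0.991 among themselves. Library 8 lay nearest to them, with 0.791 to library 3 and 0.875 to library 4. The lowest value among the 7, 0.941, was between libraries 6 and 8, so the 7 were not uniform. Library 3 had the fewest reads on the genes of the table, which is not its sequencing depth. The value of 1 read was 1.18 and 1.14 normalized counts in libraries 3 and 4, within the 0.724 to 1.96 of the others. A difference in the table totals, which thinning removes, is argued against. With all libraries thinned to 1790670 reads, the gap between the lowest correlation among the 7 and the highest of library 3 or 4 with them was 0.064, against 0.066 before. Of the 3 measured sort markers, Ly6a and Itga2b divided the libraries in the same way. Ly6a had 4256 and 5772 in libraries 3 and 4 and at most 187 in the others. Itga2b had 1616 and 6543 against at least 45798. Kit was also highest in libraries 3 and 4, with 481 and 279, but without a clear gap. Library 8 had 198 of Kit, and the rest had at most 67.4. No biological explanation, a difference in sorted cell type included, was tested, since no row has a label.

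The low values of cell division genes in libraries 3 and 4 were weighed against the deposited scaling. The median gene of libraries 3 and 4 lay 0.60 and 0.33 above the geometric mean of all libraries on the log2 scale, and that of the other 7 between -0.11 and 0.02, so the deposited scaling does not centre the genes of this table. One low factor for a library would lower all of its genes, and the lower of these offsets, 0.33, is above the highest of the other 7, 0.02. The 29 S phase and G2/M genes had median offsets of -3.41 and -1.53 in libraries 3 and 4, and of 0.00 to 1.15 in the others. This argues against too low a scaling of libraries 3 and 4 as the whole source of the order.

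Several imprinted genes stood among the widest ranges, such as Meg3 with 16.4, 19.6, 900, 4332, 8.69, 16.8, 12.3, 40.9 and 9.42 in row order. Snrpn reached 281 and Snurf 290 (159 and 164 without library 3), but they share a transcript and are not separate evidence. A hypothesis was that imprinted genes as a class have wide ranges. The 6 measured imprinted genes that passed the filter and had not been noticed first had a median range of 19.5-fold against 8.84-fold in matched random lists, at the 86.24th percentile. Leaving out the noticed genes because of their ranges works against the hypothesis. With them, 10 genes lay at the 100th percentile with a median of 65.8-fold, which is biased in its favour. The hypothesis was thus not borne out by the test set before, and the biases of both versions keep them from deciding it.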
